A study of Homo sapiens with 6 samples.

How the data were processed

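The study profiled the chromatin binding of CCNE1 (cyclin E1, the partner of the kinase CDK2 at the G1/S transition of the cell cycle) by chromatin immunoprecipitation followed by sequencing (ChIP-seq) in H7 and H9, which are established human embryonic stem cell lines. Per the labels, all 6 libraries came from cells grown in 5iLA, a medium used to hold human embryonic stem cells in a naive state of pluripotency. The labels describe 2 CCNE1 ChIP libraries from H7, which differ in the antibody (ab7959 or ab133266) and in genotype (wild type or control shRNA), 2 H7 input libraries, 1 CCNE1 ChIP library from H9 (ab7959) and 1 H9 input library. OCT4 binding, named in the design text of the series, was not analysed here.

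The deposited data analysed here are 2 headerless peak lists, one for the whole series and one attached to the H9 ChIP library. Per the submitters' processing notes, Bowtie2 2.1.0 and MACS2 2.1.0 were used with the genome build hg19. The step each served, the settings, the control libraries and the libraries behind each list are not given in the sources used here. Labels of H7 samples name the list of the series, and the name of that list holds the word combine. The list of the series has 9 columns. The authors' score of each peak equals the whole part of 10 × −log10 q in all 1303 lines of the deposited list. The column in the place of the fold in the MACS2 layout was read as the deposited fold enrichment (a ratio of ChIP to background), and the last columns as the deposited −log10 p and −log10 q. Each is the authors' own value per peak and was used here only to rank or describe peaks within the list. Whether each value describes the whole width of a peak or its highest point is not given in the sources used here. No read counts or library depths were used here, so the depth behind each peak is unknown and no counting interval of a peak's height can be given.

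The H9 list was compared line by line with the list of the series. All 1303 lines were equal in every column both lists hold, so the lists were counted as 1 list, with no replicate list and no comparison between H7 and H9, between antibodies or between ChIP and input. Positions are given as 1-based hg19 coordinates. The genome and gene annotation of hg19 were not used here; the gene table at hand describes GRCh38.p14 and its coordinates were not applied to these peaks. The planned analyses of promoters, nearest genes, CCNE1 and POU5F1 themselves, the fixed gene lists (naive, core and primed pluripotency, G1/S and replication, trophectoderm, endoderm, mesoderm, neuroectoderm and ubiquitous genes), sequence motifs and repeats were therefore not run, and peaks are named by position. The rule for named peaks, fixed before the data were examined, was the 10 peaks with the highest authors' score, with −log10 q ordering equal scores.

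Peaks per Mb were computed for each of the 22 autosomes over the span from the first to the last peak of that chromosome, in place of the ungapped chromosome length that had been planned. Each count was tested against its share of the summed span with a two-sided exact binomial test, with Benjamini-Hochberg adjustment over the 22 tests and a threshold of 0.05. Intervals are exact 95% Poisson intervals for densities and Clopper-Pearson intervals for shares, and cover counting error only. Tests added after the list had been examined were those of neighbouring peaks, densest windows, peak width against score, peak numbering, peaks against gene number per autosome, short peaks per autosome, and −log10 p at like fold. Neighbouring pairs closer than a given gap were set against 10000 random placements of the peaks within the span of their own chromosome (one-sided), and against 10000 sets in which each peak was moved by up to 500 kb. Short peaks were defined as 75 bp or less and compared by Fisher's exact test, and medians and correlations over peaks by two-sided permutation tests with 100000 resamples. The densest windows of 1 Mb were set against the maximum in 1000 random placements, of peaks and of peaks merged within 10 kb. The trend of −log10 p on fold was a quadratic fitted repeatedly to the peaks within 0.5 of it, and the interval of the difference from it came from 10000 bootstrap resamples of peaks. Peaks are not biological replicates, so each p-value describes this list alone. The density and neighbour tests were tested on simulated data of 1256 peaks over the 22 autosomes. Chromosomes 19 and 22, simulated at 2.5-fold density, were each recovered in at least 98% of 200 runs. Chromosome 17 at 2-fold was recovered in 99%, and chromosomes 4 and 8 at 0.5-fold in at least 98.5%. No effect was simulated on any other chromosome, and none as small as those seen on chromosomes 10 and 20. At least 1 chromosome was called in 4.5% of runs with uniform density. The simulated peaks were placed independently, as the binomial test and Poisson intervals assume. The peaks of the list lie closer together than that, so these rates need not hold for it. For the neighbour test, 5% of 40 runs without clustering gave a p under 0.05. With 60 neighbour pairs planted in 1 run, 62 pairs were found (one-sided p over random placements = 0.001996). Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used. The alternatives merged peaks within 10 kb, left out the longest peak-free interval of each chromosome, or kept only the upper 50% by −log10 q or the peaks wider than 75 bp. For neighbouring pairs, peaks within 1 kb were also merged first. For short peaks, the limit was also 60 or 100 bp, the strongest class the top 5% or 20% or the top 10% by fold, and peaks at the smallest width were left out. For gene number, peak numbers from the first to the last peak of each chromosome replaced the listed peaks.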

Results

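CCNE1 binding sites in naive-state human embryonic stem cells were described by 1303 peaks, of which 1256 lay on the 22 autosomes and 47 on chromosome X. The list deposited for the H9 ChIP library held the same 1303 peaks as the list of the whole series, with equal positions, peak numbers and scores in 1303 of 1303 lines, and was counted with it as 1 list. The list therefore carries no difference between H7 and H9 cells, and none of the values below can be assigned to one cell line, antibody or library. There was no replicate list and no depth, so no peak has an error of its own.

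The peaks were narrow and of modest enrichment. Their median width was 133 bp (quartiles 68 and 199 bp, range 49 to 1177 bp), and together they covered 203 kb of hg19. The authors' fold enrichment had a median of 4.49 (quartiles 4.17 and 4.98, range 3.76 to 9.13), and 74 peaks reached 6-fold or more. The median −log10 q was 1.77, and the weakest peak had a q of 0.0955. A q under 0.05 was reached by 1063 peaks (81.6%) and a q under 0.01 by 492 (37.8%). Peak numbers ran up to 3751, and 2448 of these numbers were not in the list, which held 34.7% of them. Of the numbers from the first to the last peak of each autosome, the share listed ranged from 27.7% on chromosome 16 to 45.7% on chromosome 18, and did not differ detectably between autosomes (permutation test of the chi-square statistic, p = 0.155).

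The strongest CCNE1 site was on chromosome 10 at 79799541 to 79799763 (223 bp), with a fold enrichment of 9.13 and a −log10 q of 10.32. A second peak of the list lay in the same cluster, which extended from 79793176 to 79799763. The next strongest was on chromosome 15 at 88379934 to 88379988, only 55 bp wide, with 8.43-fold enrichment and a −log10 q of 9.46. Chromosome 2 held 3 of the 10 highest-scoring peaks. The site at 233476268 to 233476522 (255 bp) had 8.18-fold enrichment, the site at 32518397 to 32518450 (54 bp) 6.99-fold and the site at 38190553 to 38190611 (59 bp) 7.04-fold. Chromosome 3 contributed the site at 42104700 to 42104957 (258 bp), with 8.19-fold enrichment. Chromosome 4 contributed a site at 84864088 to 84864203 (116 bp) with 7.94-fold enrichment, and a site at 123734176 to 123734230 (55 bp) with only 4.05-fold enrichment but a −log10 q of 7.66. The other 2 of the 10 were on chromosome 17 at 66600875 to 66600926 (52 bp, 5.95-fold) and on chromosome 18 at 49308899 to 49308952 (54 bp, 7.87-fold). None of the 5 widest peaks was among these 10. They included the 1177 bp peak on chromosome 22 at 21756547 to 21757723 (4.62-fold, −log10 q 1.98), the 985 bp peak on chromosome 18 at 77005479 to 77006463 (5.60-fold, −log10 q 3.42) and the 697 bp peak on chromosome 2 at 208675647 to 208676343 (6.20-fold, −log10 q 4.15). Gene names at these sites were not analysed here.

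The peaks were spread unevenly over the chromosomes. Chromosomes 17, 19, 20 and 22 carried more peaks than their share of the sequence spanned, with 234 peaks where 109 were expected, and chromosomes 4, 8, 10 and 13 carried fewer, with 144 where 251 were expected. Chromosomes 17, 19 and 22 are known to be rich in genes, and 4 and 13 to be poor in them. Some other autosomes did not follow this. Chromosomes 11 and 16, also among the 5 most gene-rich, stood at 1.18 and 1.19 times their expected numbers and did not pass the threshold. Nor did chromosome 18, which had the fewest genes per Mb of span (3.50), at 0.879 times. Sparse chromosomes 8 and 10 had 5.37 and 5.49 genes per Mb, close to chromosomes 2 and 3 (5.48 and 5.56), which did not pass it. Chromosome 19 was densest, with 1.29 peaks per Mb (95% interval 1.01 to 1.62), 2.73 times the expected number, followed by chromosome 22 with 1.17 (0.832 to 1.60) and chromosome 17 with 0.925 (0.726 to 1.16). Chromosome 20 had 0.777 peaks per Mb (0.573 to 1.03). The sparsest were chromosome 13 with 0.223 (0.130 to 0.357) and chromosome 8 with 0.233 (0.159 to 0.331), against 0.472 over all autosomes. Chromosome 4 had 0.281 and chromosome 10 had 0.321. By the exact binomial test the adjusted p was 1.11e-12 for chromosome 19, 9.54e-07 for 17, 4.23e-06 for 22 and 0.00307 for 20. Among the sparse chromosomes the exact binomial test gave an adjusted p of 5.19e-05 for chromosome 8, 0.000122 for 4, 0.00242 for 13 and 0.0219 for 10. The other 14 autosomes did not pass the threshold. With peaks within 10 kb counted as 1, chromosome 20 went from 1.65 to 1.45 times its expected number (exact binomial adjusted p = 0.0559) and chromosome 10 from 0.681 to 0.704 times (0.0524), so that neither passed it. Among the upper 50% by −log10 q the only sparse chromosome past it was 4, while chromosomes 8, 10 and 13 stood at 0.602, 0.629 and 0.607 times their expected numbers. Among peaks wider than 75 bp, chromosome 13 stood at 0.270 times its expected number, against 0.472 over all peaks.

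**Figure D1:**
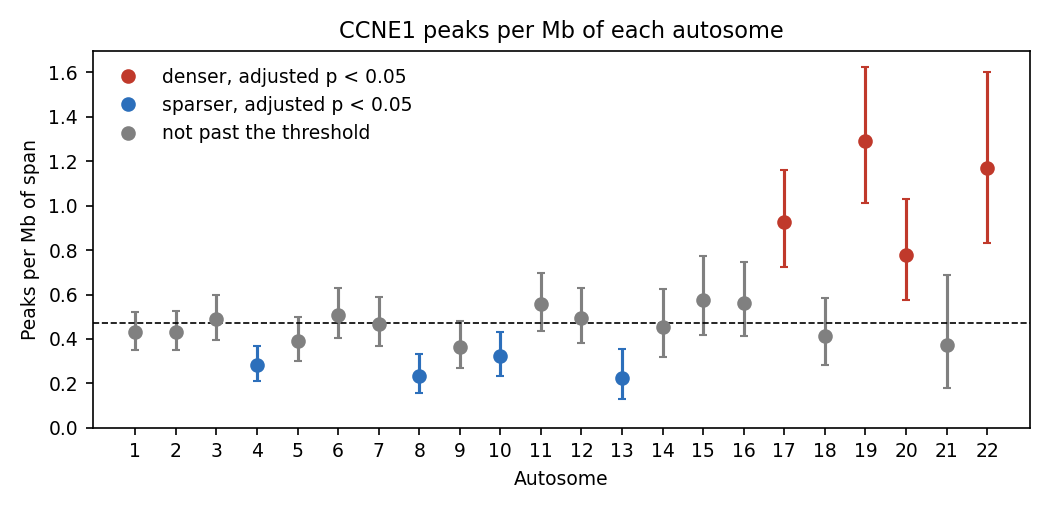
CCNE1 peaks per Mb of span (vertical axis) for each of the 22 autosomes (horizontal axis), with exact 95% Poisson intervals as bars and the mean over all autosomes, 0.472 per Mb, as a dashed line. Chromosomes 17, 19, 20 and 22 (red) lie above the line and 4, 8, 10 and 13 (blue) below it, past an adjusted p of 0.05.

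CCNE1 peaks lay close to one another more often than randomly placed peaks. The median gap between neighbours was 914 kb, yet 71 neighbouring pairs were less than 10 kb apart, against 7.09 ± 2.64 (SD over 10000 random placements), a 10.02-fold excess. At that distance, 137 peaks fell into 66 clusters, and the remaining 1166 stood alone. The 5 clusters of 3 peaks were on chromosome 11 at 113720528 to 113730713, chromosome 14 at 89898729 to 89908222, chromosome 18 at 56513302 to 56518237, chromosome 20 at 20801507 to 20802980 and chromosome 22 at 17715121 to 17725264. Gaps under 1 kb accounted for 29 of the pairs. Gaps under 100 kb were found for 206 pairs, against 68.01 ± 7.74 (SD over random placements). The permutation p was 0.0001 at each of these distances, the smallest that 10000 placements can give. When each peak was moved by up to 500 kb, which keeps the regional density, the excess was 5.21-fold under 10 kb and 1.66-fold under 100 kb (permutation p = 0.0001 for both). With peaks within 1 kb merged first, as if single sites had been split, the excess under 10 kb over random placements was 6.229-fold (permutation p = 0.0001). The densest windows of 1 Mb held 8 peaks each, on chromosome 19 from 53516019 to 54393036 and on chromosome 2 from 42722100 to 43444868. The next densest held 7, on chromosome 11 from 64609984 to 65556033. A window of at least 8 peaks occurred somewhere in the genome in 31 of 1000 random placements, but this largely repeats the excess of neighbouring pairs: with peaks within 10 kb counted as 1 the first 2 windows held 6 and 5 sites, and at least 6 occurred in 485 of 1000.

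**Figure D2:**
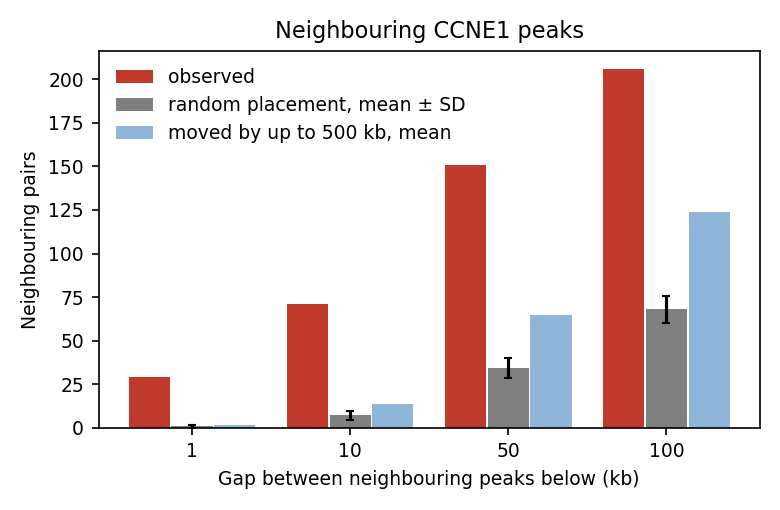
Number of neighbouring CCNE1 peak pairs (vertical axis) with a gap below 1, 10, 50 or 100 kb (horizontal axis), as observed (red), in random placements within each chromosome (grey, mean with SD) and with each peak moved by up to 500 kb (blue, mean). The observed 71 pairs under 10 kb compare with 7.09 in random placements and 13.6 after local moves.

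Short peaks were over-represented among the peaks with the highest −log10 q. Of the 131 peaks in the top 10% by −log10 q, 63 (48.1%, 95% interval 39.3 to 57.0) were 75 bp or shorter, against 303 of the other 1172 (25.9%, 23.4 to 28.5). The odds ratio was 2.65 (1.81 to 3.90; Fisher's exact test, two-sided, p = 3.27e-07). Of the 366 short peaks, 178 had the smallest width of the list, 49 bp. Without these 178 the odds ratio was 3.35 (Fisher's exact test, p = 8.33e-08), so the excess did not come from them. The highest-scoring 10 peaks included 6 short peaks, on chromosomes 2, 4, 15, 17 and 18. Short peaks had a median −log10 q of 1.96 and wider peaks of 1.70, a difference of 0.26 (permutation test, p = 1e-05, the smallest that 100000 resamples can give). Over all 1303 peaks no relation of width with −log10 q was detected (Pearson's r = −0.0059, permutation p = 0.832, adjusted 0.83; Spearman's rho = −0.03, permutation p = 0.228, adjusted 0.34). Across the 937 wider peaks, width rose with −log10 q (Pearson's r = 0.17, permutation p = 2e-05, adjusted 6e-05; Spearman's rho = 0.21, permutation p = 1e-05, adjusted 3e-05; 6 relations computed). No such relation was detected across the 366 short peaks (r = −0.05, permutation p = 0.39, adjusted 0.58; rho = −0.01, permutation p = 0.904, adjusted 0.99). These are relations across peaks of 1 list, and peaks are not independent replicates. Width and −log10 q also come from the same peak call, whose settings are not given. A relation made by the calling itself could therefore not be told apart from one of the binding sites.

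**Figure D3:**
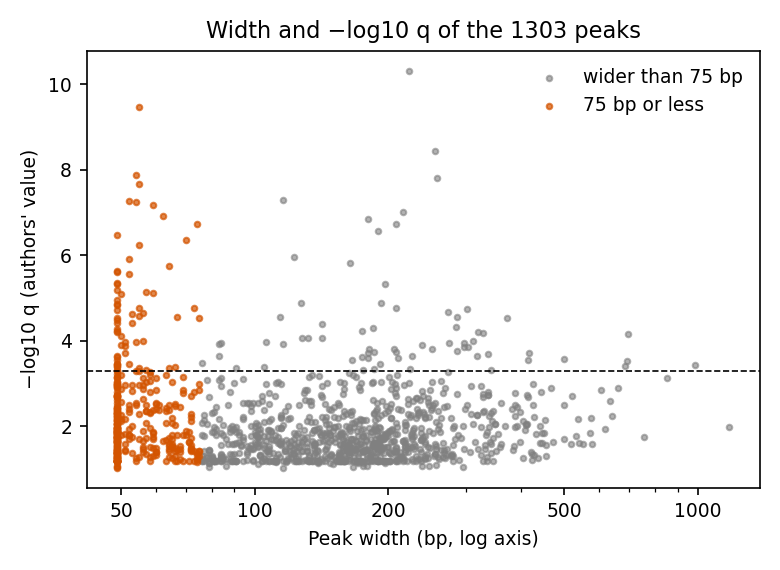
Width in bp (horizontal log axis) and the authors' −log10 q (vertical axis) of each of the 1303 peaks, with peaks of 75 bp or less in orange and wider peaks in grey. The dashed line marks the start of the top 10%, above which 63 of 131 peaks are short.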

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

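The alternatives other than the merging of peaks within 10 kb and the overlap rules were chosen after seeing the data. The overlap rules say nothing about stability, because the lists are equal and each rule returns 100% by construction. The number of sparse autosomes was 1 in the upper 50% by −log10 q, against 4 over all peaks; fewer peaks were tested there. The number of dense autosomes was 3 with merged peaks and 4 in the other settings. With peaks wider than 75 bp only, chromosome 10 stood at 0.724 times its expected number and no longer passed the threshold (exact binomial adjusted p = 0.157). The excess of pairs under 10 kb ranged from 5.21-fold to 14.2-fold, and the odds ratio of short peaks in the strongest class from 1.92 to 4.29. Neighbouring peaks carried consecutive numbers 1.08 times as often as in random subsets of the numbers (permutation p = 0.0049), and 0.989 times with peaks within 10 kb counted as 1 (permutation p = 0.63). That merging removes the neighbours closest to each other, so a fall is built into it. Over the peak numbers from the first to the last peak of each chromosome, listed or not, the partial correlation with gene number was 0.8405, against 0.8049 for listed peaks, and chromosome 18 stood at 1.395 times its share by gene number, against 1.804. No replicate could be left out, because the list is not divided by library. The random placements and circular shifts planned for the overlap of the lists, the comparisons of shared with unshared peaks, and every alternative that needs an annotation or sequence of hg19 were not run. The unknown depth limits what can be said of the absence of a peak: a site not in the list may have been bound below the threshold, or left out with the 2448 numbers that are missing.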

Other observations

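The merging of neighbouring peaks was planned before the data were examined. The other tests in this part were chosen after the list had been seen. Those of gene number over listed peaks and of short peaks on gene-rich autosomes were chosen before their values had been computed. The test of gene number was chosen for a density pattern already seen, in which several chromosomes known to be rich in genes were dense. A positive correlation could therefore be foreseen, and its p-value is not independent support. Chromosome 18 had the most peaks per 100 protein-coding genes, 11.9 (95% Poisson interval 8.11 to 16.7), 1.80 times its share by gene number, and among the listed peaks was the only autosome past the threshold on that scale (exact binomial adjusted p = 0.0374). Chromosomes 3 (1.34 times, exact binomial adjusted p = 0.0504) and 1 (0.783 times, 0.0527) lay just outside the threshold. Merging of peaks within 10 kb was not applied on that scale. The size of the excess on chromosome 18 may depend on the unstated filter. The list held 45.7% of the peak numbers between the first and last peak of chromosome 18 (95% interval 33.7 to 58.1), against 35.34% over the autosomes. The listed share did not differ detectably between autosomes, so an effect of the filter on chromosome 18 was not shown. Over the 3554 numbers so counted, listed or not, chromosome 18 stood at 1.395 times its share by gene number (exact binomial adjusted p = 0.0213). The count leaves out 82 numbers outside the spans of the chromosomes. The threshold was also passed by 8 other autosomes. Chromosomes 3, 7, 20 and 22 stood above their share (1.20, 1.23, 1.35 and 1.30 times). Chromosomes 8, 11, 19 and 21 stood below it (0.799, 0.7155, 0.693 and 0.540 times). By span chromosome 18 stood at 0.679 times its share. Chromosome 19, densest per Mb, had 5.03 listed peaks per 100 genes (3.94 to 6.33), and chromosome 8 had 4.34 (2.95 to 6.16). Gene numbers were taken from the chromosome assignments of 19122 autosomal genes in the GRCh38.p14 table, without coordinates.

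The hypothesis for the uneven density was that a chromosome's peak number follows its number of protein-coding genes: over the 22 autosomes the partial correlation of the 2 log numbers, given log span, was 0.805 for Pearson's r (permutation p = 2e-05) and 0.87 for Spearman's rho (permutation p = 1e-05), and r was 0.829 without chromosomes 18 and 19. The spread between autosomes fell from a coefficient of variation of 52.0% per Mb to 26.5% per gene. Peak number was not proportional to gene number, however. Over all numbers, listed or not, chromosome 19 stood at 0.693 times its share by gene number and chromosome 22 at 1.30 times. Splitting of single sites was argued against for chromosomes 17, 19 and 22: 3 of the 4 dense autosomes stayed past the threshold after merging, while chromosome 20 went from 1.65 to 1.45 times its expected number. The unstated filter was argued against as well, since all 4 dense autosomes held more peak numbers, listed or not, than their share and chromosomes 4, 8, 10 and 13 held fewer (0.5285, 0.597, 0.783 and 0.579 times), but 5 others passed the threshold by number and not in the list, which has fewer peaks to test: chromosomes 2, 9, 15, 16 and 18, at 0.834, 0.801, 1.30, 1.52 and 0.679 times their share by number and 0.916, 0.771, 1.22, 1.19 and 0.879 times in the list. GC content, open chromatin and extra chromosome copies in the cultures all remain open, untested.

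Whether the short peaks, in excess among the strongest sites, lie elsewhere in the genome than wider ones could not be decided: short peaks were on the 5 most gene-rich autosomes (11, 16, 17, 19 and 22) in 23.7% of cases and wider ones in 24.8%, with an odds ratio of 0.941 (0.695 to 1.27; Fisher's exact test, p = 0.715). By autosome, 10 of 17 peaks on chromosome 13 were short (58.8%, against 27.9% over the autosomes; Fisher's exact test, p = 0.0106, adjusted 0.234), and the shares over the 22 autosomes gave a chi-square of 26.7 (permutation p = 0.183). Whether a high local background, with a strong p at a modest fold, accounts for part of them could not be decided. At like fold, −log10 p of the short peaks in the top 10% was higher by 0.0947 in median (bootstrap 95% interval 0.0309 to 0.146, permutation p = 0.00643). Against the 51 peaks nearest in fold it was higher by 0.0264 (permutation p = 0.102), for the 106 of 131 peaks where that could be computed. These peaks were selected by −log10 q, which goes with −log10 p, so the comparison is conditioned on its outcome. In the top 10% by fold, the odds ratio of short peaks was 2.39 (Fisher's exact test, p = 5.13e-06). Fold and −log10 p ranked the peaks nearly alike (Spearman's rho = 0.983), so the ranking by fold is not separate support. No sequence was used here to test repeats or mappability, and no biological explanation was tested.

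Of the 8 peaks whose −log10 p lay at least 2 above the trend with fold, 7 were short. All 8 were in the top 10% by −log10 q, where 48.1% of peaks were short, against 28.1% over all peaks. With so few peaks, the count was not tested. The farthest was the chromosome 4 site at 123734176 to 123734230, 8.16 above the trend, followed by the chromosome 17 site at 66600875 to 66600926 (4.13) and the chromosome 19 site at 8850902 to 8850950 (4.04).

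The H9 list equals the list of the series in all 1303 lines, peak numbers with their gaps included. Separate calls from separate libraries would differ, so these cannot be 2 independent lists. Labels of H7 samples name the list of the series, and the name of that list holds the word combine. The same peaks are attached to the H9 ChIP library. Which libraries went into the list, from H7, from H9 or from both, is not given in the sources used here. Agreement between the cell lines cannot be read from it. The smallest width, 49 bp, was shared by 178 peaks, while no other width was shared by more than 12, and no gap between neighbours was under 200 bp.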
